A study of Mus musculus with 16 samples.

How the data were processed

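Total RNA from mouse liver had been extracted with Trizol, cleaned on columns and labelled as biotinylated cRNA, per the labels' protocols, and hybridised to Illumina mouse arrays with 1 colour. The deposited table of the whole series gives, for 25697 probes on 16 arrays, the intensity of each probe on a linear scale, not normalized between arrays and not background subtracted as far as the values show. Beside each intensity the same table gives the detection p-value deposited by the authors, in steps of 1 in 798. GenomeStudio is named per the submitters' processing notes, and its version is not given in the sources used here. The series value table holds a normalized intensity per probe and array, made by the authors with a method that is not given in the sources used here. Its scale was worked out by setting each column against the same array's signal: the rank correlation was 1 on each array and the column medians were 190.9 to 191.1, so the values are linear and aligned between arrays with no centring of genes, and whether background was subtracted stays unknown. The groups were taken from the genotype and agent in the labels, and the doses, the times after treatment and the slides are not given in the sources used here.

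Values were computed in R 4.3.3 with limma 3.58.1. The background was corrected by normexp with negative control intensities inferred from the detection p-values (neqc, offset 16), followed by quantile normalization and log2. Probes with a detection p-value under 0.05 on at least 2 arrays were kept, 15411 in all. Gene symbols came from the platform annotation: 23978 probes had 1 symbol, 1719 had none and 0 had several. Of these, 23962 matched the gene table of the mouse reference by Entrez number, which changed 0 symbols. For a gene with several kept probes the probe with the highest mean was used, and a probe without a symbol counted as its own feature, which left 11338 tested features, 10436 of them with a symbol and called genes here together with the other 902. Of 47 values from other probes of named genes, 3 had the opposite sign, and 0 of those passed an unadjusted p of 0.05. A group was taken as not above background for a gene where the probe used had no detection p-value under 0.05 on its arrays, and fold changes against it are given as a lower bound, from the lowest detected signal of those arrays.

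A model of group means was fitted over all groups, so that they share 1 estimate of the spread, with empirical Bayes moderation (7 residual degrees of freedom and 3.76 prior ones). The 12 comparisons were the effect of each agent in each genotype, the 2 interactions, the knockout effect under each agent and over both vehicles, and oil against saline. P-values are two-sided and were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. The plan had treated all 16 arrays as separate samples. The 2 knockout saline arrays were then found to show no difference beyond noise, since the differences of 2 probes of a gene between them were uncorrelated, and were averaged, giving 15 samples; this was decided after the data and the counts from 16 samples had been seen, and those counts are given as an alternative. In all, 34 gene lists with at least 5 measured members, of metabolic and stress pathways and of markers of liver cell types, were tested with camera, with a preset correlation of 0.01 and again with an estimated one, and adjusted over the 34 lists of a comparison. Counts adjusted over the list alone apply Benjamini and Hochberg to the members' limma p-values. Results are described for a part of the lists, mainly those that passed in every fit leaving out 1 array. Leaving out either knockout saline array keeps their sample in the fit, so no fit was without it. Leaving out any other array leaves 1 sample in its group. Calls and counts can then fall from lost precision alone, so a lost call does not by itself single out that array.

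The groups, comparisons, tests, gene lists and first set of alternatives were chosen before the data were examined, as was the rule for named genes. That rule takes the 10 highest and 10 lowest log2 fold changes among called genes whose samples do not overlap for the agents in the wild-type, the interactions and the averaged knockout effect, with no demand on overlap for interactions, and the 5 highest and lowest for the other comparisons. Where none passed it takes the 3 smallest p-values, and in each described list up to 4 called members or else the 2 with the smallest p-values. A set of genes was always included, among them Stk11, Cyp2e1, Glul, Nr1i3, G6pc and Pck1. The alternatives were no background correction, median centring, the authors' normalized values, no probe filter, a stricter one (detection p-value under 0.01 on at least 8 arrays), every kept probe, trended and robust variance, array weights, the arrays compared alone, the replicate number as a block, and leaving out each array in turn. The arrays compared were taken as all oil and CCl4 arrays, all saline and AICAR arrays, or all vehicle arrays, in both genotypes. They included groups outside most of the comparisons. Counting the knockout saline arrays as 2 samples, as first planned, became an alternative when they were averaged, after the data had been seen. Leaving out arrays for the lists was also added then. So was the test of the knockout effect in oil against that in saline, which is not among the 12 comparisons. A slide block was not run, since no slide is given.

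The fit was tested on simulated data for 11338 genes, with spreads drawn from the fitted prior and a set of genes changed by known amounts. For the CCl4 effect in the wild-type it recovered 22.4% of the changes of 1 log2 unit, 80.6% of those of 2 and 95.5% of those of 3, with 7 unchanged genes called. For the AICAR effect in the knockout the shares were 13.4%, 70.1% and 95.5%, with 4 unchanged genes called, and for the knockout effect over both vehicles 50.7%, 98.5% and 98.5%, with 4. Each simulated gene varied independently, with the same spread in every group. In the data the median SD within a group was 0.264 in wild-type oil and 0.142 in wild-type saline. The shares therefore do not give the sensitivity in the noisier groups, such as oil.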

Results

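Gene expression was measured in the livers of male FVB mice aged 10 weeks, which were wild-type or carried a liver-specific knockout of LKB1 (gene symbol Stk11), a kinase that activates the AMP-activated protein kinase AMPK. The mice had received carbon tetrachloride (CCl4), a liver toxicant that cytochrome P450 enzymes activate, or its vehicle mineral oil, or AICAR, a nucleoside that cells convert into an activator of AMPK, or its vehicle saline. The 2 genotypes and 4 agents gave 8 groups of 2 arrays each, 16 arrays in all. The median probe signal lay between 172.4 and 213.7 across arrays, and 12233 to 13730 of the 25697 probes were detected above background on an array. The labels call the arrays of a group biological replicates but tie none to a separate animal, so the p-values measure only the spread between these samples, and whether it arises between animals or in preparing the RNA is not known here. The small number of arrays limits the precision of every value.

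Stk11 signal, on the normalized log2 scale, lay between 10.04 and 10.38 on the 8 wild-type arrays and between 8.94 and 9.54 on the 8 knockout arrays. The knockout minus wild-type difference for Stk11 was -1.16 ± 0.19 (SE, 2 against 2 samples) in oil, -1.14 ± 0.23 in saline (1 against 2), -0.91 ± 0.19 under CCl4 and -0.94 ± 0.19 under AICAR, with limma adjusted p = 0.018, 0.15, 0.046 and 0.014. The oil call was lost without wild-type oil replicate 2 or either knockout oil array. It was also lost with array weights and when only the oil and CCl4 arrays were fitted (limma adjusted p up to 0.11). The call under CCl4 was lost without any 1 of its 4 arrays (highest adjusted p = 0.24) and in 3 of 11 alternative fits, and that under AICAR without either wild-type AICAR array or knockout AICAR replicate 2 (highest adjusted p = 0.095). Over both vehicles the difference was -1.15 ± 0.15 with adjusted p = 0.0036, and it passed the threshold without any 1 of the 6 arrays of the other vehicle groups. The knockout saline sample itself could not be left out. Where the Stk11 probe lies relative to the deleted exons is not known here, so a remaining signal does not measure remaining LKB1. The 2 knockout saline arrays showed no difference beyond noise: over 848 pairs of probes for the same gene, the differences between the 2 arrays were uncorrelated (r = -0.012, 95% interval -0.08 to 0.055), whereas the lowest such r among the other 119 array pairs was 0.48. They were therefore counted as 1 sample, which leaves that group with no spread of its own, although the labels call them biological replicates.

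**Figure D1:**
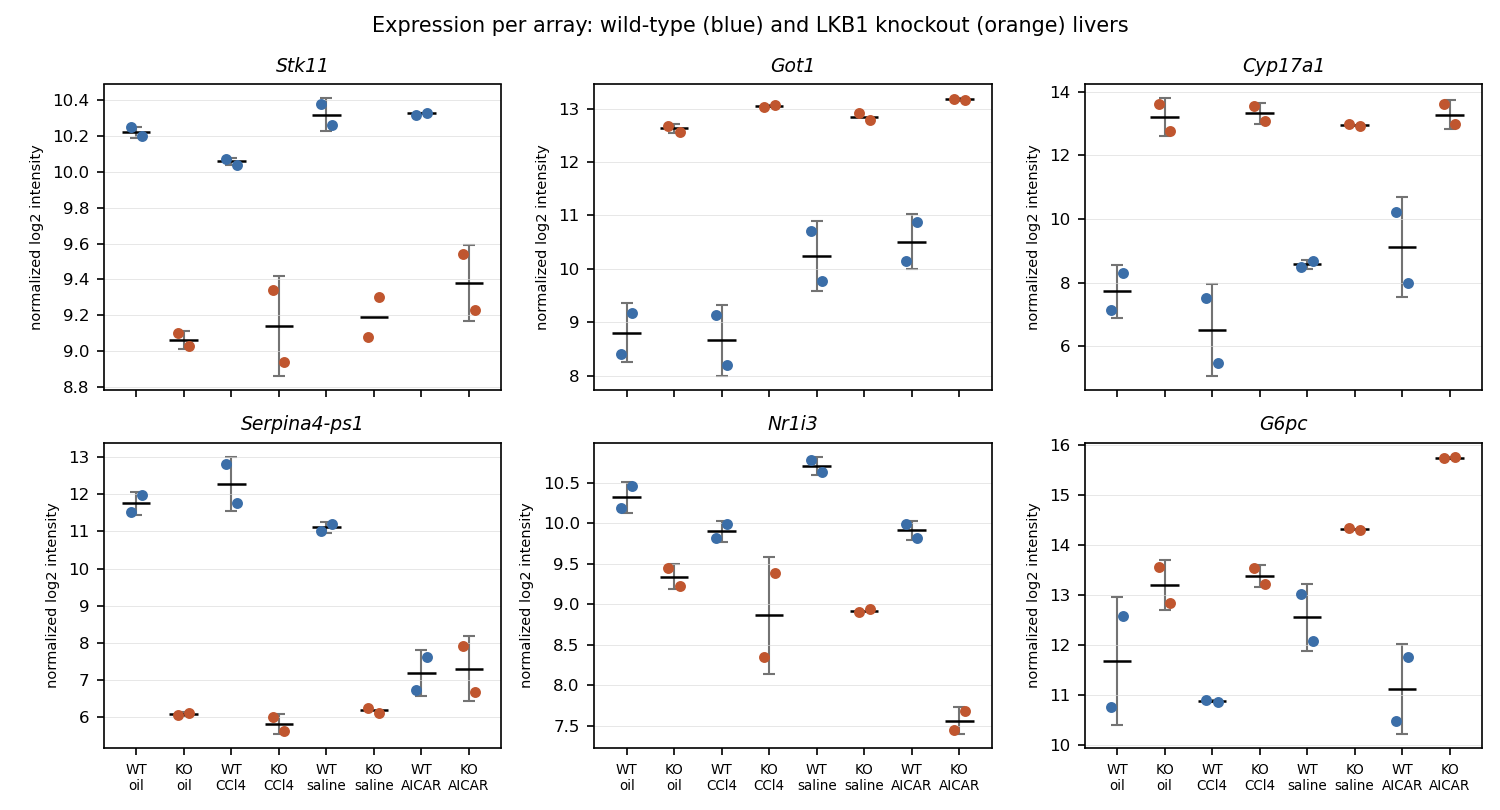
Normalized log2 intensity (y axis) of Stk11, Got1, Cyp17a1, Serpina4-ps1, Nr1i3 and G6pc in each group (x axis), with 1 point per array, black lines for group means and grey bars for the SD of the 2 arrays, except in the knockout saline group, whose arrays count as 1 sample. Stk11 on every knockout array, at 9.54 or below, was under every wild-type array, at 10.04 or above.

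The comparison of the genotypes without an active agent asked which liver genes depend on LKB1. Cyp17a1, the steroid 17-alpha-hydroxylase, averaged 7.72 ± 0.83 (SD, n = 2) in wild-type oil livers and 13.2 ± 0.59 (n = 2) in knockout oil livers, and over both vehicles it rose by 4.93 ± 0.6 log2 units (SE; adjusted p = 0.0028; 3 knockout against 4 wild-type samples). Tff3, a secreted mucosal peptide, rose by 4.67 ± 0.47 (adjusted p = 0.00079), Nnmt, which methylates nicotinamide, by 4.02 ± 0.44 (adjusted p = 0.0014), and Egln3, an oxygen-sensing prolyl hydroxylase, by 3.79 ± 0.3 (adjusted p = 0.00011), although a second Egln3 probe gave only 0.6. Serpina4-ps1 fell by 5.31 ± 0.35 (adjusted p = 5.4e-05). Obp2a, an odorant-binding protein, fell by 4.73 ± 0.56 (adjusted p = 0.0023) and Dio1, a thyroid hormone deiodinase, fell by 2.99 ± 0.37 (adjusted p = 0.0029). Serpina4-ps1 is annotated as a pseudogene of a large gene family, and whether its probe also binds related transcripts was not examined. Hsd3b5, a steroid dehydrogenase, fell by 4.92 ± 0.83 (adjusted p = 0.015), but this call was lost without either wild-type saline array (highest adjusted p = 0.057). Nr1i3, the xenobiotic receptor CAR, fell by 1.39 ± 0.23 (adjusted p = 0.013), and this call was lost without wild-type saline replicate 1 (adjusted p = 0.056). In all, limma called 150 of 11338 genes, 88 higher and 62 lower in the knockout. The count was 85 without wild-type saline replicate 1, 90 without wild-type saline replicate 2, 67 when only the vehicle arrays were fitted and 433 when both knockout saline arrays were counted as samples, as had been planned.

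Amino acid metabolism was among the gene lists that passed with higher values, with the preset correlation only. Of 29 measured genes of the urea cycle and amino acid catabolism, 23 were higher and 6 lower in the knockout vehicles; 4 rose over all genes tested and 11 when adjusted over the list alone. Those called included Cth, which makes cysteine from cystathionine (2.27 ± 0.3, SE; adjusted p = 0.004), and Cbs, which makes cystathionine (1.54 ± 0.24, adjusted p = 0.0098). The list's median was 0.4 log2 units, with camera's adjusted p = 5e-08 and adjusted p = 0.52 with an estimated correlation. Among 15 gluconeogenesis genes 12 were higher and 3 lower, with 1 called over all genes, Got1 (cytosolic aspartate aminotransferase, 3.22 ± 0.32, adjusted p = 0.00074), and 5 adjusted over the list alone. Camera gave gluconeogenesis genes adjusted p = 0.00056, and adjusted p = 0.52 with an estimated correlation. The 24 interferon response genes were higher in 22 cases and lower in 2, with a median of 0.77 (0 called over all genes and 4 adjusted over the list alone). Camera gave interferon genes adjusted p = 3.7e-06, and adjusted p = 0.52 with an estimated correlation. In the mitochondrial respiratory chain 37 of 40 genes were higher and 3 lower, by a median of 0.19 (0 called over all genes and 0 adjusted over the list alone). Camera gave respiratory chain genes adjusted p = 2.4e-05, and adjusted p = 0.52 with an estimated correlation. Of 32 phase I xenobiotic metabolism genes, 21 were lower and 11 higher; 4 fell over all genes and 7 adjusted over the list alone. Camera gave phase I genes adjusted p = 0.00052, and adjusted p = 0.52 with an estimated correlation. Markers of sinusoidal endothelial cells, another cell type of the liver, also had lower values: 23 of 27 were lower and 4 higher, by a median of -0.21 (0 called over all genes and 0 adjusted over the list alone). Camera gave sinusoidal markers adjusted p = 0.001, and adjusted p = 0.52 with an estimated correlation. In this comparison 7 of 34 lists had higher and 4 lower values past the threshold with the preset correlation, and 0 did with an estimated one. That last count was 0 in each of the 12 comparisons.

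The genotypes were also compared within each vehicle. In oil, 141 genes were called, 78 higher and 63 lower, and in saline 15, 11 higher and 4 lower, while 12 genes were called in both, all in the same direction, against 0.187 for independent lists. Both comparisons use 1 shared estimate of each gene's spread, so 0.187 may be too low a reference. In oil Got1 rose by 3.83 ± 0.4 (SE; adjusted p = 0.0017), whereas Glul, the glutamine synthetase of pericentral hepatocytes, was at least 2.67-fold lower (adjusted p = 0.0065; such bounds set the brighter group's mean against the lowest detected signal on the arrays of a group that is not above background). This call was lost without knockout oil replicate 2. It was also lost when only the oil and CCl4 arrays were fitted (limma adjusted p = 0.057). In saline the axon guidance receptor Robo1 rose by 3.55 ± 0.32 (adjusted p = 0.0021), while Glul gave 0.32 ± 0.31 (adjusted p = 1). Interferon response genes in oil were higher for 22 of 24 members and lower for 2, with a median of 1.32; 1 rose over all genes and 12 adjusted over the list alone. Camera gave interferon genes adjusted p = 2.1e-08, and adjusted p = 0.53 with an estimated correlation. In saline 18 of the 24 were higher and 6 lower, with a median of 0.14 (0 called over all genes and 0 adjusted over the list alone). Camera gave the interferon list adjusted p = 0.43, and adjusted p = 0.99 with an estimated correlation. The knockout effect in oil minus that in saline passed limma's threshold for 0 genes, with 478 at an unadjusted p under 0.05, where 567 are expected by chance, so no difference between vehicles was shown. The oil count was 35 with array weights, 33 when only the oil and CCl4 arrays were fitted, 212 in the authors' normalized values and 218 without background correction. Among the leave-outs it fell most without knockout oil replicate 2 and without wild-type oil replicate 2. The saline count was 7 without wild-type saline replicate 1 and 2 without wild-type saline replicate 2; with both knockout saline arrays as samples the counts were 243 in oil and 94 in saline.

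CCl4 was compared with mineral oil in each genotype to ask how the toxicant changed the liver and whether LKB1 altered that response. Genes of pericentral hepatocytes, the zone around the central vein that activates CCl4, had lower values than in oil. No single gene passed the threshold, and their list passed only with the preset correlation. Slc1a2, a glutamate transporter, averaged 8.88 ± 2.02 (SD, n = 2) in wild-type oil livers and was not above background after CCl4. By the group means it was at least 9.65-fold lower there (adjusted p = 0.35), and in the knockout at least 11.9-fold lower (adjusted p = 0.57). These bounds take no account of the spread between the oil arrays, so they do not bound the change from each array. In wild-type livers the difference was -2.19 ± 0.35 (SE) for Oat, -1.31 ± 0.25 for Glul and -1.76 ± 0.48 for Cyp2e1, the main enzyme activating CCl4 (adjusted p = 0.35, 0.35 and 0.43). In the knockout Cyp2e1 gave -0.61 ± 0.48 (adjusted p = 1). The glucose transporter Slc2a2, from the list of glycolysis and glucose use, gave -1.84 ± 0.28 (adjusted p = 0.57) in the knockout. That value comes from 1 probe. For the AICAR by genotype interaction this probe gave 2.67, and each of the other kept Slc2a2 probes gave 0.74. Limma called 0 genes in the wild-type, 0 in the knockout and 0 for the interaction, with 1058, 403 and 463 genes at an unadjusted p under 0.05 against 567 expected by chance. Each count was also 0 in all 11 alternative fits, apart from leaving out arrays. Leaving out wild-type oil replicate 1 gave 2 genes in the wild-type, leaving out knockout oil replicate 2 gave 6 in the knockout and 6 for the interaction, and leaving out knockout CCl4 replicate 2 gave 1 in the knockout. Arrays of a group were far apart in oil and in knockout CCl4: over probes detected on every array with a mean log2 above 9, the SD of the log2 differences was 0.578 within wild-type oil, 0.481 within knockout oil, 0.527 within knockout CCl4 and 0.372 within wild-type CCl4, but 0.333 between wild-type oil replicate 1 and wild-type CCl4 replicate 2, and 0.302 between knockout oil replicate 2 and knockout CCl4 replicate 2. The counts of 0 therefore do not show that CCl4 had no effect.

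Gene lists after CCl4 were tested on the same arrays, so the pericentral list describes that pattern again and is no separate support. In wild-type livers 22 of 24 pericentral markers were lower and 2 higher, by a median of -1.12 log2 units; 0 were called over all genes and 7 fell when adjusted over the list alone. Camera gave pericentral markers adjusted p = 1.9e-11, and adjusted p = 0.095 with an estimated correlation. In the knockout 20 were lower and 4 higher, by a median of -0.54 (0 called over all genes and 2 adjusted over the list alone). Camera gave the pericentral list adjusted p = 6.2e-07, and adjusted p = 0.27 with an estimated correlation. The difference between the genotypes had a median of 0.57, with 17 higher, 7 lower, 0 called over all genes and 1 adjusted over the list alone. Camera gave the pericentral difference adjusted p = 0.013, and adjusted p = 0.6 with an estimated correlation. That difference was lost without wild-type oil replicate 2, knockout oil replicate 2, wild-type CCl4 replicate 1 or knockout CCl4 replicate 2 (highest adjusted p = 0.46). Unfolded protein response genes in the wild-type were higher for 21 of 23 members and lower for 2, by a median of 0.59 (0 called over all genes and 2 adjusted over the list alone). Camera gave unfolded protein response genes adjusted p = 1.6e-07, and adjusted p = 0.095 with an estimated correlation. Interferon response genes in the knockout were lower for 23 of 24 members and higher for 1, by a median of -0.96 (0 called over all genes and 5 adjusted over the list alone). Camera gave interferon genes adjusted p = 6e-18, and adjusted p = 0.27 with an estimated correlation. Their interaction was -1.41, with 23 members lower, 1 higher, 0 called over all genes and 8 adjusted over the list alone. Camera gave the interferon interaction adjusted p = 4.6e-16, and adjusted p = 0.49 with an estimated correlation. For urea cycle and amino acid catabolism the interaction was 0.5, with 27 of 29 higher, 2 lower, 0 called over all genes and 2 adjusted over the list alone. Camera gave the urea cycle interaction adjusted p = 2.1e-08, and adjusted p = 0.55 with an estimated correlation. Phase I genes in the knockout were lower for 26 of 32 members and higher for 6, by a median of -0.33 (0 called over all genes and 1 adjusted over the list alone). Camera gave phase I genes adjusted p = 7.1e-08, and adjusted p = 0.27 with an estimated correlation.

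For markers of cells other than hepatocytes, 3 lists had higher and 1 lower values after CCl4 in wild-type livers past the threshold with the preset correlation. Of 30 stellate cell and fibroblast markers 23 were higher and 7 lower, by a median of 0.31 (0 called over all genes and 3 adjusted over the list alone). Camera gave stellate cell markers adjusted p = 0.02, and adjusted p = 0.66 with an estimated correlation. Of 15 cholangiocyte markers 11 were higher and 4 lower, by a median of 0.4 (0 called over all genes and 0 adjusted over the list alone). Camera gave cholangiocyte markers adjusted p = 0.029, and adjusted p = 0.58 with an estimated correlation. Both were lost without wild-type oil replicate 2 or wild-type CCl4 replicate 2 (highest adjusted p = 0.94 for each). Of 27 sinusoidal endothelial markers 18 were higher and 9 lower, by a median of 0.21 (0 called over all genes and 0 adjusted over the list alone). Camera gave sinusoidal markers adjusted p = 0.041, and adjusted p = 0.54 with an estimated correlation. These were lost without either wild-type oil array or wild-type CCl4 replicate 2 (highest adjusted p = 0.35), with the stricter probe filter and with the replicate numbers as a block. All 6 pancreatic acinar markers were lower and 0 higher, by a median of -0.3 (0 called over all genes and 0 adjusted over the list alone). Camera gave acinar markers adjusted p = 0.033, and adjusted p = 0.43 with an estimated correlation. This was lost without either wild-type oil array or wild-type CCl4 replicate 2 (highest adjusted p = 0.19), without background correction, in the authors' normalized values and without the probe filter (up to 0.49).

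In the knockout 3 such lists had higher values after CCl4. Of 30 stellate cell and fibroblast markers 29 were higher and 1 lower, by a median of 0.32 (0 called over all genes and 0 adjusted over the list alone). Camera gave stellate cell markers adjusted p = 0.00046, and adjusted p = 0.7 with an estimated correlation. This was lost without knockout oil replicate 1, where the median was -0.16 (adjusted p = 0.57), and without knockout CCl4 replicate 2 (adjusted p = 0.51). Of 27 sinusoidal endothelial markers 22 were higher and 5 lower, by a median of 0.2 (0 called over all genes and 0 adjusted over the list alone). Camera gave sinusoidal markers adjusted p = 0.0034, and adjusted p = 0.41 with an estimated correlation. These were lost without knockout CCl4 replicate 2 (adjusted p = 0.15). Of 13 neutrophil markers 8 were higher and 5 lower, by a median of 0.2 (0 called over all genes and 0 adjusted over the list alone). Camera gave neutrophil markers adjusted p = 0.046, and adjusted p = 0.7 with an estimated correlation. They were lost without knockout oil replicate 2 (adjusted p = 0.76) and without knockout CCl4 replicate 2, where the median was -0.17 (adjusted p = 0.59).

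**Figure D2:**
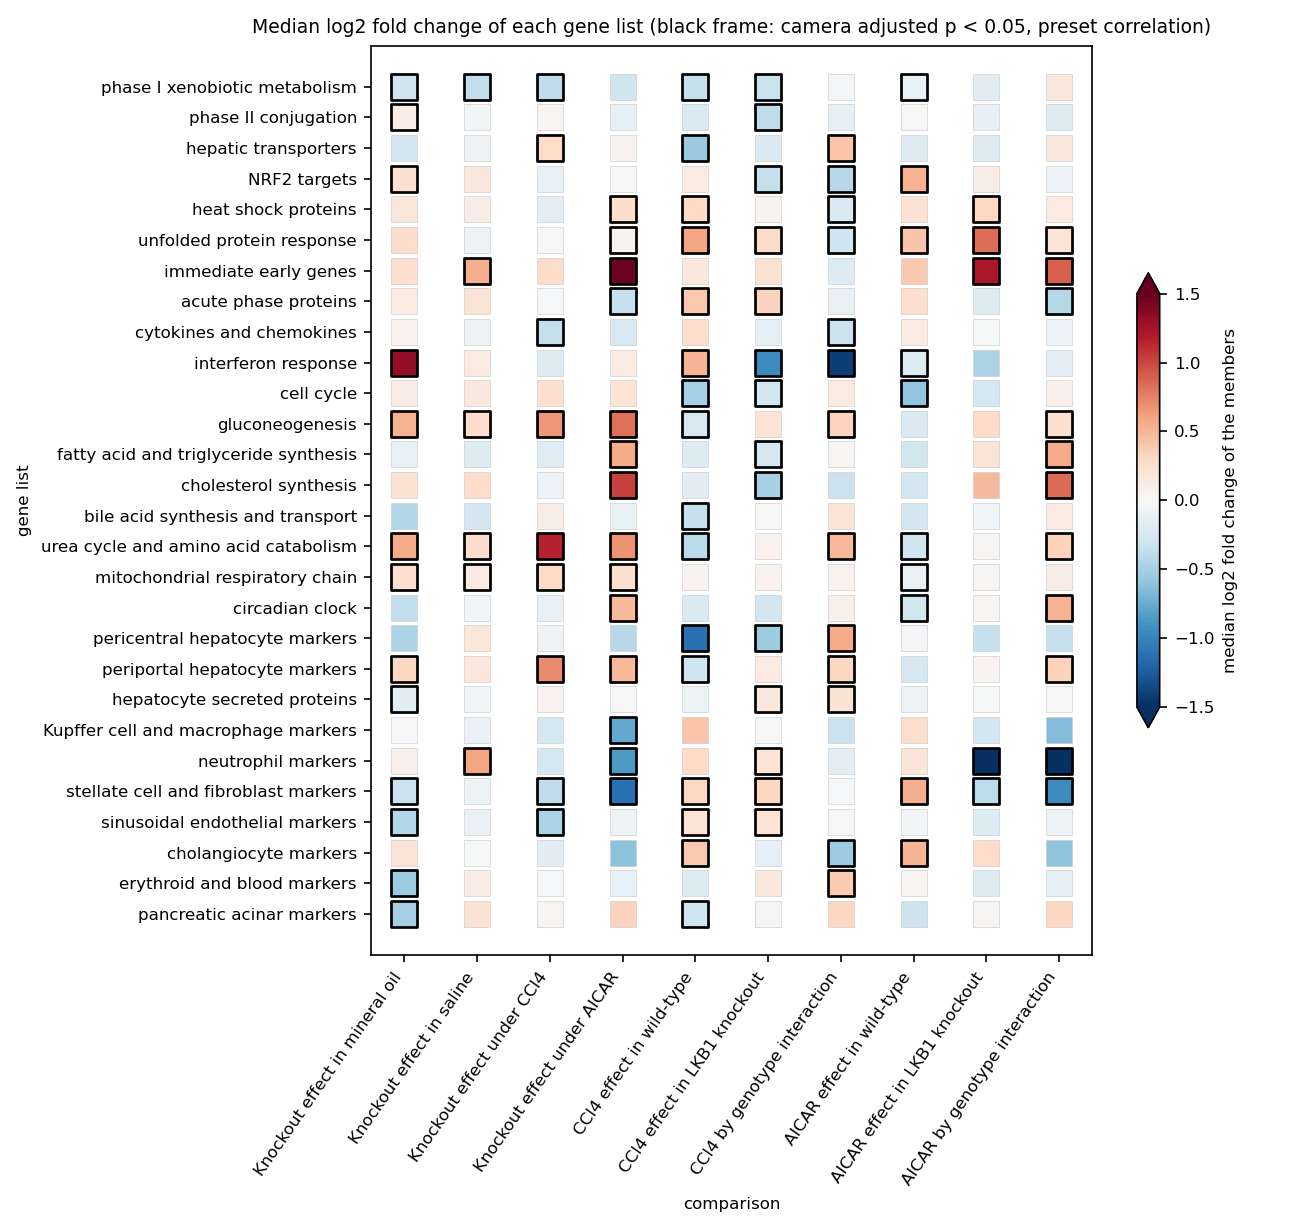
Median log2 fold change (colour) of the measured members of each gene list (y axis) in each comparison (x axis), with black frames where camera with a preset correlation gave an adjusted p under 0.05; with an estimated correlation 0 of 34 lists passed in any comparison. Urea cycle and amino acid catabolism had a median of 1.15 for the knockout effect under CCl4, and pericentral markers one of -1.12 for CCl4 in the wild-type.

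Knockout and wild-type livers were also set against each other after CCl4. Cyp17a1 rose by 6.81 ± 0.76 log2 units (SE, 2 against 2 samples; adjusted p = 0.0019), and the amino acid enzymes Got1, Oat, Cth and Agxt rose by 4.39 ± 0.4, 3.83 ± 0.35, 3.8 ± 0.38 and 2.71 ± 0.35 (adjusted p = 0.00041, 0.00041, 0.001 and 0.004). Oat, at 15.81 and 15.85 on the knockout CCl4 arrays, was near the top of the measured range, so its rise may be understated. The sulfotransferase Sult1a1 rose by 3.5 ± 0.31 (adjusted p = 0.00041), and Kiss1, which encodes kisspeptin, was at least 13.4-fold higher (adjusted p = 0.00033). Serpina4-ps1 fell by 6.5 ± 0.45 (adjusted p = 0.00023). H2-Aa, a class II histocompatibility gene, fell by 5.7 ± 1.15 (adjusted p = 0.041), a call that was lost without any 1 of the 4 arrays (highest adjusted p = 0.3). It was also lost without the probe filter, with trended and robust variance and with the replicate numbers as a block. Fitting only the oil and CCl4 arrays lost it too (limma adjusted p up to 0.19 over these fits). For such polymorphic genes a sequence difference between animals can lower a probe's signal. All 29 measured genes of the urea cycle and amino acid catabolism were higher and 0 lower, by a median of 1.15; 11 rose over all genes and 20 adjusted over the list alone. Camera gave urea cycle genes adjusted p = 6.7e-24, and adjusted p = 0.17 with an estimated correlation. Of 22 periportal markers 15 were higher and 7 lower; 5 rose over all genes, and 10 rose and 1 fell adjusted over the list alone. Camera gave periportal markers adjusted p = 3.9e-06, and adjusted p = 0.33 with an estimated correlation. Sinusoidal endothelial markers were lower for 23 of 27 members and higher for 4, by a median of -0.48 (0 called over all genes and 7 adjusted over the list alone). Camera gave sinusoidal markers adjusted p = 7.7e-07, and adjusted p = 0.17 with an estimated correlation. Limma called 146 genes, 95 higher and 51 lower, of which 69 were also called in oil, all in the same direction, against 1.82 for independent lists. These comparisons share no arrays, but they share 1 estimate of each gene's spread, so 1.82 may be too low a reference. The count was 40 when only the oil and CCl4 arrays were fitted and 222 with both knockout saline arrays as samples. It was lower in each fit that left out 1 of the wild-type or knockout CCl4 arrays.

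AICAR was compared with saline in livers with and without LKB1, and AMPK activity was not measured. In wild-type livers the single gene that passed the threshold was Serpina4-ps1, which fell by 3.94 ± 0.45 (SE, 2 against 2 samples; adjusted p = 0.034), with 1210 genes at an unadjusted p under 0.05. This call was lost without any 1 of the 4 arrays (highest adjusted p = 0.44). The wild-type count was 219 with array weights, 38 when only the saline and AICAR arrays of both genotypes were fitted, 2 in the authors' normalized values, 2 without background correction, 0 without the probe filter and 0 with the replicate numbers as a block. NRF2 target genes, which answer oxidative stress, were higher for 19 of 22 members and lower for 3, by a median of 0.53 (0 called over all genes and 1 adjusted over the list alone). Camera gave NRF2 targets adjusted p = 0.0021, and adjusted p = 0.64 with an estimated correlation. Unfolded protein response genes were higher for 17 of 23 members and lower for 6 (0 called over all genes and 4 adjusted over the list alone). Camera gave unfolded protein response genes adjusted p = 0.0015, and adjusted p = 0.64 with an estimated correlation. Cell cycle genes were lower for 21 of 26 members and higher for 5, by a median of -0.59 (0 called over all genes and 0 adjusted over the list alone). Camera gave cell cycle genes adjusted p = 0.0015, and adjusted p = 0.64 with an estimated correlation. Markers of cholangiocytes, the cells lining bile ducts, had higher values: 13 of 15 were higher and 2 lower, by a median of 0.51 (0 called over all genes and 3 adjusted over the list alone). Camera gave cholangiocyte markers adjusted p = 0.0015, and adjusted p = 0.64 with an estimated correlation. Of 30 stellate cell and fibroblast markers 25 were higher and 5 lower, by a median of 0.54 (0 called over all genes and 0 adjusted over the list alone). Camera gave stellate cell markers adjusted p = 0.0046, and adjusted p = 0.64 with an estimated correlation, a result that was lost without wild-type saline replicate 1 (adjusted p = 0.11).

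In the knockout, AICAR was followed by higher levels of stress and immediate early genes. Hspa5, the main chaperone of the endoplasmic reticulum, rose by 2.64 ± 0.33 (SE, 2 against 1 samples; adjusted p = 0.0038) and Nfil3, a transcription factor of the circadian clock, by 2.23 ± 0.26 (adjusted p = 0.0027). Hspa5 was also higher after AICAR in the wild-type, at 9.49 and 9.42 against 7.8 and 7.36 in saline, without a call there. The immediate early gene Fosb was at least 5.91-fold higher (adjusted p = 0.0019) and Fosl1 at least 3.49-fold (adjusted p = 0.0055). Gp5, known from platelets, rose by 3.87 ± 0.27 (adjusted p = 0.00028), Ampd1, an AMP deaminase, by 3.69 ± 0.34 (adjusted p = 0.0011) and Gzmm, a granzyme, by 3.61 ± 0.42 (adjusted p = 0.0027). Igf2 fell by 2.58 ± 0.4 (adjusted p = 0.011), a call that was lost without knockout AICAR replicate 1. Igf2 was highest in the knockout saline sample, at 11.01 and 11.08 on its arrays, against 9.72 and 9.84 on the knockout oil arrays. The knockout AICAR arrays, at 8.29 and 8.64, were near the wild-type saline arrays, at 8.35 and 8.7. The size of the fall therefore rests on that 1 baseline sample. Among 19 immediate early genes 18 were higher and 1 lower; 5 rose over all genes and 9 adjusted over the list alone (median 1.22). Camera gave immediate early genes adjusted p = 4.5e-12, and adjusted p = 0.13 with an estimated correlation. Of 23 unfolded protein response genes 19 were higher and 4 lower; 4 rose over all genes and 8 adjusted over the list alone (median 0.84). Camera gave unfolded protein response genes adjusted p = 6.3e-09, and adjusted p = 0.062 with an estimated correlation. Neutrophil markers were lower for 12 of 13 members and higher for 1 (median -1.63; 0 called over all genes and 0 adjusted over the list alone). Camera gave neutrophil markers adjusted p = 0.00019, and adjusted p = 0.87 with an estimated correlation. The knockout saline sample that serves as the baseline was itself high in these markers, such as Ngp, at 8.2 and 8.29 on its arrays against 6.87 and 7.74 in wild-type saline livers, so the difference cannot be put down to AICAR alone. In saline 10 of the 13 were higher and 3 lower in the knockout (median 0.59; 0 called over all genes and 0 adjusted over the list alone). Camera gave the neutrophil list adjusted p = 0.029, and adjusted p = 0.99 with an estimated correlation. This was lost without wild-type saline replicate 1 (adjusted p = 0.3), without knockout saline replicate 1 (adjusted p = 0.081) and without the probe filter (adjusted p = 0.27). Limma called 136 genes, 112 higher and 24 lower, with the spread of the single saline sample taken from the other groups; the count was 84 without knockout AICAR replicate 1, 54 without knockout AICAR replicate 2 and 652 with both knockout saline arrays as samples.

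Whether AICAR acted differently in the genotypes was tested as an interaction, the knockout effect of AICAR minus the wild-type effect. It passed the threshold for 34 genes, 28 positive and 6 negative, with 1039 at an unadjusted p under 0.05. When only those arrays were fitted it was 43 genes, 20 of them positive, so the share of positive calls depended on the fit. Gp5 differed by 3.5 ± 0.35 (SE; adjusted p = 0.0098), the receptor kinase Epha2 by 3.97 ± 0.49 (adjusted p = 0.016), Nfil3 by 2.92 ± 0.33 (adjusted p = 0.016), the phosphatase Dusp1 by 2.82 ± 0.46 (adjusted p = 0.035) and Acnat2 by -3.07 ± 0.43 (adjusted p = 0.022). Dusp1 went from 12.07 ± 0.15 (SD, n = 2) to 11.23 ± 0.14 (n = 2) in the wild-type and from 12.64 (n = 1) to 14.63 ± 0.25 (n = 2) in the knockout. Serpina4-ps1 differed by 5.05 ± 0.71 (SE; adjusted p = 0.022), being low in knockout livers with and without AICAR, at 7.29 ± 0.88 (SD, n = 2) and 6.18 (n = 1). Gp5 lost its call without wild-type saline replicate 2 or wild-type AICAR replicate 2, Epha2 without these or wild-type AICAR replicate 1, and Nfil3 and Serpina4-ps1 without any 1 of the wild-type saline and AICAR arrays. Acnat2 lost it without those or knockout AICAR replicate 2, and Dusp1 without those or either knockout AICAR array; the highest adjusted p of these genes was 0.15, for Dusp1. Dusp1 was also lost with the replicate numbers as a block (adjusted p = 0.059), and Acnat2 and Serpina4-ps1 when only those arrays were fitted (adjusted p = 0.051 for each). The count was 2 without wild-type saline replicate 1, 0 without wild-type saline replicate 2, 2 without wild-type AICAR replicate 1, 0 without wild-type AICAR replicate 2, 14 without knockout AICAR replicate 1 and 11 without knockout AICAR replicate 2. It was 118 with both knockout saline arrays as samples, 59 with array weights, 21 with a stricter probe filter and 17 with the replicate numbers as a block.

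Among the gene lists, immediate early genes had an AICAR by genotype median of 0.9, with 16 of 19 higher and 3 lower; 3 were called over all genes, Fosb, Fosl1 and Dusp1, and 4 adjusted over the list alone. Camera gave immediate early genes adjusted p = 1.2e-05, and adjusted p = 0.72 with an estimated correlation. Fatty acid and triglyceride synthesis genes had a median of 0.57, with 21 of 24 higher and 3 lower (0 called over all genes and 0 adjusted over the list alone). Camera gave fatty acid synthesis genes adjusted p = 0.0064, and adjusted p = 0.72 with an estimated correlation. Markers of neutrophils and of stellate cells and fibroblasts went the other way. All 13 neutrophil markers were lower and 0 higher, by a median of -1.59 (0 called over all genes and 0 adjusted over the list alone). Camera gave neutrophil markers adjusted p = 6e-05, and adjusted p = 0.72 with an estimated correlation. Of 30 stellate cell and fibroblast markers 26 were lower and 4 higher, by a median of -0.96 (0 called over all genes and 1 adjusted over the list alone). Camera gave stellate cell markers adjusted p = 5.8e-05, and adjusted p = 0.72 with an estimated correlation. Within the knockout 27 of these 30 were lower after AICAR and 3 higher, by a median of -0.39 (0 called over all genes and 0 adjusted over the list alone). Camera gave the stellate list adjusted p = 0.015, and adjusted p = 0.87 with an estimated correlation, and it was lost without knockout AICAR replicate 1 (adjusted p = 0.16). The calls of Fosb and Fosl1 were lost without any 1 of the wild-type saline, wild-type AICAR and knockout AICAR arrays (highest adjusted p = 0.1 and 0.14), as was that of Dusp1 (0.15), and that of Fosl1 also when only those arrays were fitted (adjusted p = 0.059). The 4 interaction lists named here passed the threshold with the preset correlation without any 1 of the 6 arrays of the other groups. They rest on the single knockout saline sample, which was not left out and which was itself high in neutrophil markers.

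**Figure D3:**
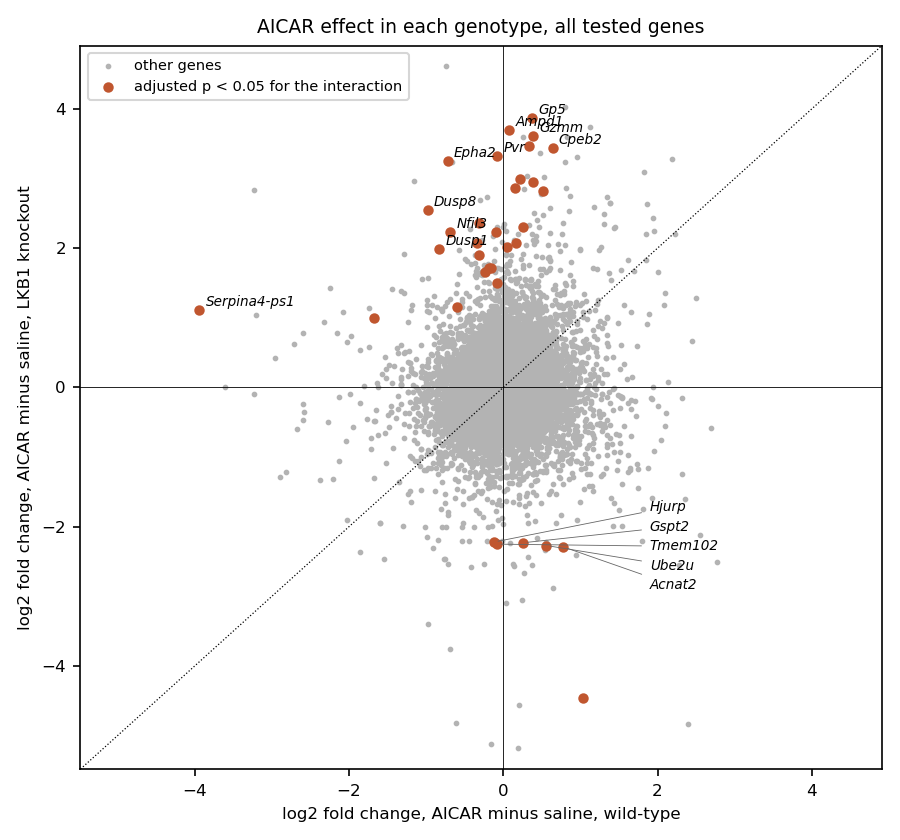
Log2 fold change of AICAR minus saline in wild-type livers (x axis) against that in knockout livers (y axis), with 1 point for each of 11338 genes, red-brown where the interaction passed the threshold and a dotted line where both effects are equal. The 34 red-brown genes include Gp5, at 0.37 in the wild-type and 3.87 in the knockout.

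After AICAR the genotypes differed in more genes than after any other agent, 854 called by limma, 456 higher and 398 lower in the knockout. G6pc, the last enzyme of glucose release, rose by 4.63 ± 0.57 (SE, 2 against 2 samples; adjusted p = 0.0011) and Igfbp1, an insulin-repressed secreted protein, by 4.45 ± 0.56 (adjusted p = 0.0012). The kinase Sik1, a member of the AMPK family, rose by 3.83 ± 0.45 (adjusted p = 0.001), Nfil3 by 3.18 ± 0.21 (adjusted p = 7.2e-05) and Atf4, a transcription factor of the stress response, by 2.26 ± 0.2 (adjusted p = 0.00023). Nr1i3 fell by 2.35 ± 0.29 (adjusted p = 0.0012) and Gas6, a ligand of receptor kinases, fell by 1.52 ± 0.22 (adjusted p = 0.0025). Nuak2, another AMPK family kinase, fell by 1.39 ± 0.22 (adjusted p = 0.0039), while Phlda2 was at least 11.9-fold lower (adjusted p = 0.00027). Each of the genes named here passed the threshold in all 4 fits that left out 1 array. Most of the 64 gene calls that the rule picked in this comparison did not, so the genes named here are not typical of them. The count was lower in every fit that left out 1 array. It was 1286 with array weights and 1394 when only the saline and AICAR arrays were fitted.

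In the same comparison all 19 immediate early genes were higher and 0 lower; 12 rose over all genes and 12 adjusted over the list alone (median 1.47). Camera gave immediate early genes adjusted p = 7.3e-12, and adjusted p = 0.29 with an estimated correlation. Among 15 gluconeogenesis genes 14 were higher and 1 lower; 7 rose over all genes and 8 adjusted over the list alone (median 0.83). Camera gave gluconeogenesis genes adjusted p = 2e-05, and adjusted p = 0.54 with an estimated correlation. All 18 cholesterol synthesis genes were higher and 0 lower, by a median of 1.02, yet 0 were called over all genes and 0 adjusted over the list alone. Camera gave cholesterol synthesis genes adjusted p = 4.9e-05, and adjusted p = 0.54 with an estimated correlation. For urea cycle and amino acid catabolism 28 of 29 genes were higher and 1 lower; 5 rose over all genes and 8 adjusted over the list alone (median 0.67). Camera gave urea cycle genes adjusted p = 6.5e-08, and adjusted p = 0.54 with an estimated correlation. Stellate cell and fibroblast markers had lower values: 27 of 30 were lower and 3 higher, and 5 fell over all genes and 16 adjusted over the list alone (median -1.12). Camera gave stellate cell markers adjusted p = 2.9e-06, and adjusted p = 0.54 with an estimated correlation. Kupffer cell and macrophage markers were lower for 17 of 19 members and higher for 2 (median -0.78; 0 called over all genes and 0 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.72 with an estimated correlation), a result that was lost without wild-type AICAR replicate 2 or knockout AICAR replicate 1 (highest adjusted p = 0.32).

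The 5 correlations of effects planned across all 11338 genes had no arrays in common between their sides, and genes are not independent replicates, so no p is given. The CCl4 and AICAR effects in wild-type livers had Pearson's r = 0.328 (Spearman's rho = 0.235), which was 0.134 without wild-type oil replicate 2 and 0.241 without wild-type saline replicate 1. The CCl4 effects in wild-type and knockout had r = 0.212 (rho = 0.184), and -0.011 without knockout oil replicate 1, 0.067 without knockout CCl4 replicate 2 and 0.319 without knockout oil replicate 2. For the AICAR effects in wild-type and knockout r was 0.089 (rho = 0.105), and it was 0.019 without knockout AICAR replicate 2 and 0.145 without knockout AICAR replicate 1. The AICAR effect in the wild-type and the knockout effect in oil had r = 0.175 (rho = 0.066), which was -0.057 without knockout oil replicate 2, 0.018 without wild-type oil replicate 2 and 0.347 without knockout oil replicate 1. The CCl4 effect in the wild-type and the knockout effect in saline had r = 0.079 (rho = 0.067), which was -0.009 without wild-type saline replicate 1 and 0.151 without wild-type saline replicate 2.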

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

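The tests on the knockout saline arrays, on antigen-presenting cells, on the loss of LKB1, on the histocompatibility region under CCl4 and on the direction of the interferon genes were chosen after the result was seen; what would count for or against was written before their values were known for the region test under AICAR, the interferon leave-outs and the splits, although the leave-outs of lists were added after the data had been seen.

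The AICAR by genotype interaction stood out because the test of the difference itself passed for 34 genes.

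The 2 knockout saline arrays stood out because they were closer to each other than any other pair, with r = 0.993 over all genes against at most 0.988 for other pairs. Between separate animals or RNA preparations, 2 probes of a gene should differ together, as they did in the other pairs, where r was 0.48 or more. Here r was -0.012, and its upper 95% bound of 0.055 lies below all of these, which argues against separate animals with the usual spread. One RNA sample on both arrays is consistent with these values, as a hypothesis. No biological explanation was tested.

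H2-Aa, H2-Eb1, H2-Bl and D17H6S56E-5 were low on knockout oil replicate 2, both knockout CCl4 and both knockout AICAR arrays, with H2-Aa between 5.98 and 7.26, against 10.73 on knockout oil replicate 1, 12.1 on both knockout saline arrays and 11.15 to 13.16 on the wild-type arrays. Fewer antigen-presenting cells are argued against by H2-Ab1 and Cd74, carried by the same cells, whose mean change under AICAR was -0.57 while H2-Aa changed by -4.88. A strain or haplotype difference at this locus between animals may lower such probes' signals. Under CCl4 13 of 100 genes of the region were called against 1.12% elsewhere (two-sided Fisher's exact p = 2.45e-10). That count includes genes of the pattern itself. It takes calls in either direction, and a call can also come from the wild-type CCl4 arrays. The excess is therefore not tied to the low knockout arrays. The test written beforehand, on the AICAR comparison, missed its threshold (exact p = 0.184); by its own wording that counted against a haplotype difference and was first read so, a reading changed afterwards because 11% in the region against 7.54% elsewhere bounds nothing. Loss of LKB1 alone is argued against by 2 of 7 knockout samples, although Stk11 was as low in these. Over the 4 genes their median difference from the wild-type mean was -1.31 on knockout oil replicate 1 and -0.01 in the saline sample. The change under AICAR was -4.3, and the SD between wild-type arrays was 0.71. The limma comparison in saline is a separate test, with an SE of up to 1.41 from the spread of all groups, and by itself decides nothing. Loss of LKB1 together with another factor stays open.

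Interferon response genes had a CCl4 by genotype median of -1.41. That 1 array decides the sign of this median is argued against by the 8 leave-outs, in which it ran from -1.98 to -0.83. Camera's highest adjusted p for the list in these was 1.4e-08 with the preset correlation. Over all arrays the list did not pass the threshold with an estimated correlation (adjusted p = 0.49). The preset correlation of 0.01 treats the list's genes as nearly independent. The leave-out p-values therefore do not show that the difference exceeds the spread between arrays. List means differed within a group too, at 9.7 and 10.67 on the knockout CCl4 arrays. The knockout oil arrays had the highest list means, 10.9 and 11.55, against 10.14 and 9.9 on the wild-type oil arrays. An effect of LKB1 loss whatever the agent cannot be told apart from none: the lowest knockout median was -0.19, under CCl4, where the list did not pass the threshold (adjusted p = 0.14, and adjusted p = 0.98 with an estimated correlation), and an earlier reading of this value as contrary was withdrawn for that reason. A difference between single animals, such as an infection, may also have raised these genes in the oil group and was not tested.

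The 7 vehicle samples were split into 3 and 4 in 34 ways, the real one included, with the other factor as a term. For the knockout effect over both vehicles 1 of 34 splits, the real one, called 108 genes, and the highest other called 2, so a split by chance is argued against as far as 34 splits can tell. For oil against saline the real one called 0 genes and the highest other 2, so that 34 of 34 splits call at least as many whatever the data, and this test decides nothing.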

How the results depend on the processing

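Averaging the knockout saline arrays was chosen after the result was seen, which turned the planned count of 2 samples into an alternative. The leave-outs of the lists were added after the data had been seen, with the reading of the interferon leave-outs written before their values were known. The other alternatives were planned.

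Counts of called genes moved by more than 1.5-fold in part of the alternatives, and the cause was not tested. The main fit gave all groups 1 spread, although spreads differed. The median SD within a group was 0.264 in wild-type oil and 0.142 in wild-type saline and in wild-type AICAR. Array weights and fits of part of the arrays, which relax this, lowered the knockout count in oil and raised that under AICAR. The main fit may thus call too many genes in oil and too few under AICAR. The AICAR effect in the wild-type (1) became 2 without background correction, 2 in the authors' normalized values, 0 with no probe filter, 219 with array weights, 0 with the replicate block and 38 when only the arrays compared were fitted. The AICAR interaction (34) became 21 with the stricter probe filter, 59 with array weights and 17 with the replicate block, and 43, of which 20 were positive against 28 of 34, with only the arrays compared. The knockout effect in oil (141) became 218 without background correction, 212 in the authors' normalized values, 35 with array weights and 33 with only the arrays compared. With only the arrays compared it became 67 over both vehicles (150), 40 under CCl4 (146) and 1394 under AICAR (854), which array weights took to 1286. The arrays compared were all vehicle, all oil and CCl4, or all saline and AICAR arrays. The knockout saline arrays as 2 samples gave 652 for AICAR in the knockout, 118 for the AICAR interaction, 243 for the knockout in oil, 94 in saline, 433 over both vehicles, 222 under CCl4, and 60 for oil against saline. A slide block was not run, since no slide is given. Median centring called 92 of 142 genes higher in the knockout in oil against 78 of 141, and 501 of 801 against 456 of 854 under AICAR.

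Leaving out 1 array gave 0 to 2 for CCl4 in the wild-type, 0 to 6 in the knockout and 0 to 6 for its interaction, and 0 to 0 for AICAR in the wild-type, 54 to 159 in the knockout and 0 to 38 for its interaction. The knockout effect ran from 32 to 159 in oil, 2 to 15 in saline, 85 to 165 over both vehicles, 40 to 105 under CCl4 and 229 to 355 under AICAR, and oil against saline from 0 to 9. The correlations ran from 0.134 to 0.363 (CCl4 and AICAR in the wild-type), -0.009 to 0.151 (CCl4 in the wild-type and knockout in saline), -0.057 to 0.347 (AICAR in the wild-type and knockout in oil), -0.011 to 0.319 (CCl4 in both genotypes) and 0.019 to 0.145 (AICAR in both genotypes), so 3 of them changed sign. Leaving out either knockout saline array keeps their sample, so these ranges include no fit without it. The other leave-outs cut a group to 1 sample, so lower counts may also come from lost precision.

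Of 124 list results 124 were lost with an estimated correlation. In the leave-outs 13 of 644 reversed in camera's direction, which need not change the sign of the median. For CCl4 in the wild-type the stellate cell median ran from 0.03 to 0.53. For CCl4 in the knockout the medians ran from -0.81 to 0.05 (NRF2 targets), -1.05 to 0.44 (cell cycle), -0.64 to -0.01 (fatty acid synthesis), -1.05 to 0.13 (cholesterol synthesis, at -0.02 without knockout CCl4 replicate 2), 0.01 to 0.22 (hepatocyte secreted proteins), -0.17 to 0.73 (neutrophil) and -0.16 to 0.7 (stellate cell). The cell cycle value of 0.44, without knockout CCl4 replicate 2, passed the threshold in the opposite direction (adjusted p = 0.00027). For cytokines the CCl4 interaction ran from -0.89 to 0.1 and the knockout effect under CCl4 from -0.79 to 0.05. For the knockout in oil the stellate cell median ran from -0.7 to -0.02, with -0.04 without knockout oil replicate 1.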

Other observations

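The test of Cyp2e1 was chosen after the result was seen; oil against saline was planned.

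In oil against saline 2 of 34 lists, both of markers of cells other than hepatocytes, had lower values past the threshold with the preset correlation, and 0 passed with an estimated one. Of 27 sinusoidal endothelial markers 22 were lower and 5 higher in oil, by a median of -0.39, with 0 called over all genes and 6 adjusted over the list alone (adjusted p = 2.2e-08, and adjusted p = 0.17 with an estimated correlation). Gpr182 differed by -0.83 ± 0.19 (SE, 4 oil against 3 saline samples; adjusted p = 0.19) and Fcgr2b, an Fc receptor, by -0.68 ± 0.17 (adjusted p = 0.23). Of 13 neutrophil markers 10 were lower and 3 higher, by a median of -0.93, with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.98 with an estimated correlation); Ngp, a granule protein, gave -1.66 ± 0.61 (adjusted p = 0.37), and it was highest on the arrays of the knockout saline sample, at 8.2 and 8.29. Limma called 0 genes for oil against saline, with 1177 at an unadjusted p under 0.05. The count was 0 in the alternative fits except 60 with both knockout saline arrays as samples, and 1 without knockout oil replicate 1 and 9 without knockout saline replicate 2. Whether oil and saline livers also differed in route or day is not given in the sources used here.

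Among kinases of the AMPK family, which LKB1 phosphorylates, 2 are set out here without a test of the difference between them. Sik1 rose in the knockout over both vehicles by 2.36 ± 0.36 (SE; adjusted p = 0.0082), under CCl4 by 3.64 ± 0.45 (adjusted p = 0.0036) and under AICAR by 3.83 ± 0.45 (adjusted p = 0.001), and each call held in every fit that left out 1 array, none of which was without the knockout saline sample, though the vehicle call did not hold when only the vehicle arrays were fitted (adjusted p = 0.07). Prkaa2, a catalytic subunit of AMPK, gave 0.07 ± 0.21, 0.1 ± 0.27 and 0.36 ± 0.27 (adjusted p = 0.94, 0.94 and 0.45). Of the 20 measured LKB1 and AMPK family kinases, under AICAR 10 were higher and 10 lower, 1 rose and 2 fell over all genes, and 1 rose and 2 fell adjusted over the list alone (adjusted p = 0.86, and adjusted p = 0.91 with an estimated correlation). The 2 that fell over all genes were Nuak2 and Stk11, the deleted gene itself.

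The smaller median change of pericentral genes after CCl4 in the knockout has a candidate explanation, as a hypothesis, in lower Cyp2e1, the enzyme that activates CCl4, before the agent was given. Cyp2e1 was 14.74 and 14.1 on the knockout oil arrays against 15.57 and 15.82 on the wild-type oil arrays, a difference of -1.28 ± 0.48 (SE) that limma did not call (adjusted p = 0.24). The test in oil therefore decides nothing, and the list difference itself was lost in 4 of the 8 fits that left out 1 array. Cyp2e1 was also lower in the knockout in saline. It was 14.73 and 14.76 on the arrays of the 1 knockout sample, against 15.85 and 15.47 on the wild-type arrays.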
